A study of Mus musculus with 45 samples.

How the data were processed

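Facial prominences were dissected from C57BL6/J mouse embryos and pooled from several embryos per sample, and per the labels the ectoderm was peeled from the mesenchyme after digestion with Dispase II. RNA was hybridized to Affymetrix Mouse Gene 1.0 ST arrays. There are 45 arrays in 15 groups of 3 biological replicates, which cover 15 of the 18 combinations of 3 ages, 3 prominences and 2 layers. The replicates are separate pools, so they carry the variation between dissections as well as between arrays. The labels give no batch or scan day. The number of arrays limits the precision of every value.

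The deposited value table holds log2 values, per the labels made with RMA in Affymetrix Power Tools 1.91, with background correction, quantile normalization and summary per transcript cluster. The values run from 1.76 to 14.72 with 2 decimals, and the array medians from 5.97 to 6.22. A deposited table of p-values for detection above background covers 35557 probe sets, and its header names apt 1.8.0. Of these, 6613 probe sets are absent from the value table and were not analysed here. The authors' model table holds Benjamini-Hochberg adjusted q-values of a linear model with interactions for 9626 probe sets, after a filter on variance. The genome build behind the probe sets is that of the manufacturer's annotation, and the reference at hand is another build, so no coordinates are given.

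Gene symbols come from the authors' model table alone. Its names were brought to current symbols, 8452 unchanged, 853 through a synonym and 92 kept as given, while 229 had none. The 8686 distinct symbols include 399 with several probe sets. Of the tested probe sets, 5201 carry no symbol, so they enter the counts but are never named, and their mean log2 signal is 5.58 against 6.84 for named ones. A gene outside that table is missing here whatever its expression.

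Probe sets with a variance above the median over all arrays (0.0414) were tested, 14472 in all. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 15 groups, and contrasts averaged the differences within each age and prominence with equal weight. Moderated tests were adjusted by Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05. The layer was compared over 7 combinations, the prominences within a layer over E11.5 and E12.5, and the ages within a layer over the prominences that have both. The effect of each factor was tested with moderated F in an additive three-factor linear model, and layer with age and layer with prominence were tested as interactions. A detection p under 0.05 counted as detected. A fold is written as at least so large where 0 arrays on the lower side detected the probe set. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the files, and matplotlib 3.10.9 drew the figures.

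The gene lists, the comparisons, the tests, the rule for naming genes and all but 3 of the alternatives were fixed before the data were examined. Named genes are those past the threshold, with a single symbol that is not a clone or small RNA name and the same sign in every age and prominence compared, ranked by absolute difference. The 10 largest in each direction are named for the layer, the 6 largest in each direction for other comparisons, and 6 in all for each interaction. From each list up to 6 members with the largest absolute differences could be named as well. Some genes that meet this rule are not reported. A few genes outside that rule are given among the other observations, where this is said.

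The 25 gene lists were tested in 12 comparisons with camera in limma at a preset correlation of 0.01 between genes, on 1 probe set per symbol, and adjusted over the lists of a comparison. Some genes sit in more than 1 list, and of the genes listed the epithelial list had 31 of 31 tested, cranial mesenchyme 26 of 26, endothelial 17 of 17, neural tube and eye 9 of 16, pharyngeal endoderm 8 of 14 and cell cycle 18 of 30. Camera called 121 of 300 pairs of list and comparison. With a correlation estimated from the data 18 of these were called, while fry, which tests whether the genes of a list move one way on balance, called 165. In 38 pairs the median, the mean and the direction of the test differed in sign, 0 of them called. Centring arrays or normalizing again by quantiles turned the mean of 0 called pairs, and of 17 and 14 others.

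Replicate numbers were checked as possible pairs of ectoderm and mesenchyme. Over 21 pairs the correlations of residuals ran from -0.42 to 0.36, and 9 matched their own number best, with a consensus correlation of 0.0156, so the numbers were not used as pairs. Alternatives were no variance filter, a detection filter, only the groups compared, trended and robust moderation, an unmoderated test, centring on array medians, quantile normalization, array weights, a block for the replicate number, and each array left out in turn. Leaving out 3 arrays that stand apart, leaving out the frontonasal groups, and centring on medians with the same probe sets tested were chosen after seeing the data.

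The procedure was tested on simulated data of the same size, 14472 probe sets with known changes. The noise was drawn independently for each probe set, with the same spread in every group. The simulation therefore lacks the correlation between genes and the noisier arrays of the real data, and does not measure false calls that come from them. Changes of 1 log2 were recovered in 100% of cases for the layer, 98.5% for mesenchyme E12.5 minus E11.5, and 92.5% for ectoderm E11.5 minus E10.5. For changes of 0.5 log2 the recovery was 98.5%, 91.0% and 40.3%. For frontonasal minus mandibular mesenchyme it was 70.1% at 0.5, and for the interaction with age 56.7%. Of the calls, 7.01% were on unchanged probe sets for the layer, 5.26% for frontonasal minus mandibular mesenchyme, 1.03% for mesenchyme E12.5 minus E11.5, 1.90% for ectoderm E11.5 minus E10.5 and 5.56% for the interaction with age. With no change in any factor, and noise independent between probe sets, there were 0 calls. Of 25 simulated lists the 1 that was shifted by 0.5 was called, and 1 of the other lists was too.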

Results

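Gene expression was measured in the ectoderm and the mesenchyme of the mouse facial prominences, the tissue buds that grow together to form the upper and lower jaw and the nose. The data are 45 Affymetrix Mouse Gene 1.0 ST arrays in 15 groups of 3 replicates. Tissue came from the frontonasal, maxillary and mandibular prominences of C57BL6/J embryos at embryonic days E10.5, E11.5 and E12.5. Both layers of all 3 prominences were measured at E11.5 and E12.5. At E10.5 the groups are frontonasal mesenchyme, mandibular mesenchyme and mandibular ectoderm. Values are log2 signals, and each array detected between 22008 and 26532 probe sets above background, or 76.0% to 91.7% of those with a value. Differences below are averages over the ages and prominences compared, in log2 units, with the standard error of the fit to all 45 arrays. A fold is given as at least that large where no array on the lower side detected the gene. List members not counted as higher or lower did not pass the threshold. Where the counts differ when adjusted over the list alone, they follow as "list alone", larger direction first.

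The series sets out to separate the effects of layer, prominence and age. In an additive model of the 3 factors, 9723 of 14472 tested probe sets differed by layer, 7212 by age and 3209 by prominence. The authors' deposited table of 9626 probe sets holds q-values under 0.05 for 7439 by layer, 5796 by age and 3961 by prominence. It also holds 3889 for the interaction of age and layer, 2407 for prominence and layer, 1753 for age and prominence, and 1549 for all 3 factors. Among the 9395 probe sets in both, 7066 of the authors' 7369 layer calls, 4793 of their 5717 age calls and 2518 of their 3946 prominence calls were also called here.

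**Figure D1:**
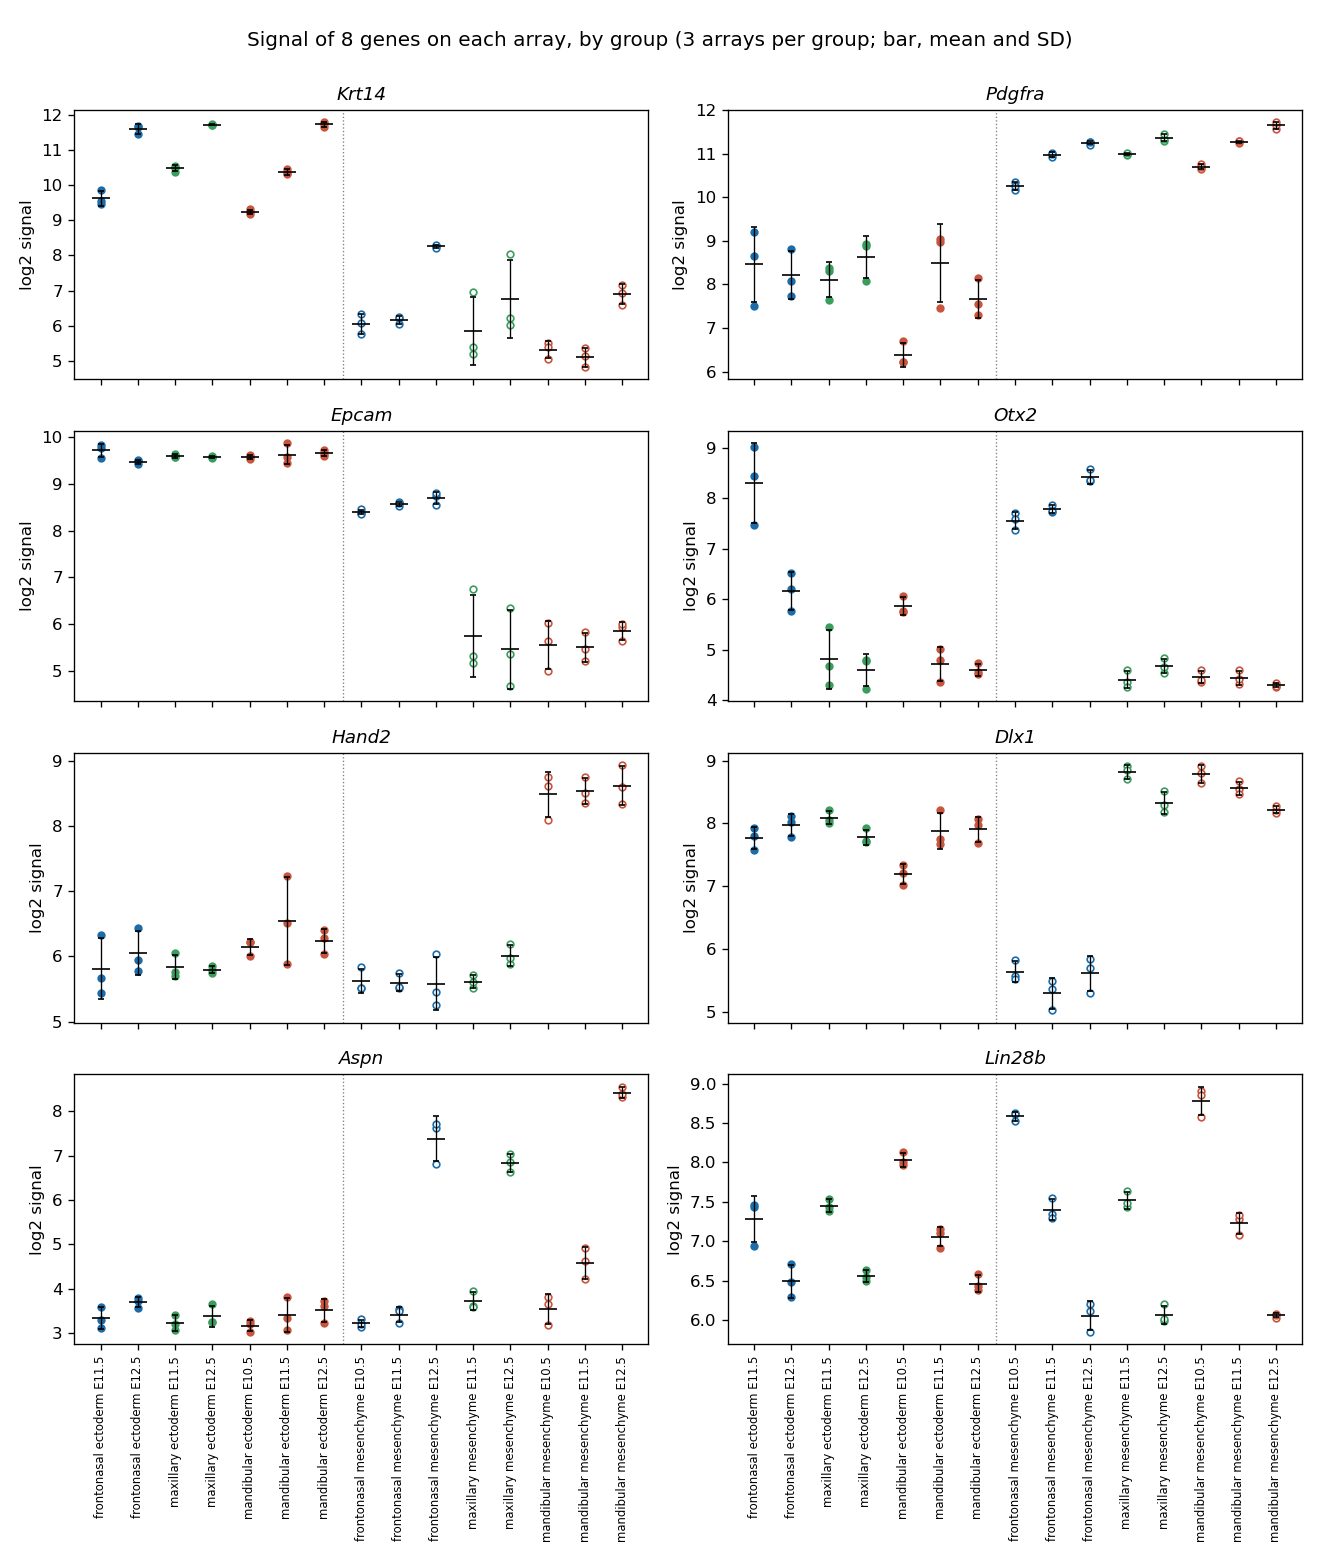
Log2 signal of 8 genes on every array, by group, with points for arrays and bars for group means; panels show Krt14, Pdgfra, Epcam, Otx2, Hand2, Dlx1, Aspn and Lin28b. Epcam and Otx2 are high in frontonasal mesenchyme, and Hand2 is high in mandibular mesenchyme.

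The ectoderm was first compared with the mesenchyme of the same age and prominence (21 arrays against 21, 7 combinations). Keratin and cell-junction genes were the most enriched in ectoderm. Krt14, a keratin of basal epithelial cells, was 20.3-fold higher (4.34 ± 0.12, probe set 10391052, adjusted p = 1.08e-27). The desmosome genes Perp (4.25 ± 0.10) and Dsp (4.17 ± 0.12) and the cadherin Cdh1 (3.79 ± 0.09) were close behind. Gabrp (4.22 ± 0.08), Esrp1, a splicing factor of epithelia (4.12 ± 0.12), Gjb2 (4.08 ± 0.10), Krt5 (3.97 ± 0.12) and Trim29 (3.82 ± 0.07) were also among the largest. Aldh1a2, an enzyme of retinoic acid synthesis, was 10.9-fold lower in ectoderm (-3.44 ± 0.12, probe set 10586865, adjusted p = 8.67e-25). The vessel genes Emcn (-3.33 ± 0.11), Cdh5 (-3.24 ± 0.09) and Kdr (-3.21 ± 0.10) were lower too. So were the mesenchymal receptors Pdgfra (-3.18 ± 0.12), Ddr2 (-3.13 ± 0.10) and Epha3 (-2.98 ± 0.12), the transcription factors Ebf1 (-3.20 ± 0.11) and Prrx1 (-3.01 ± 0.15), and Tnfaip6 (-2.99 ± 0.13). In all, 10074 probe sets differed, 5190 higher in ectoderm and 4884 lower, of which 618 and 662 differed at least 2-fold.

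Epithelial identity and junction genes were higher in ectoderm in 31 of 31 cases (camera adjusted p = 3.85e-18, 0.135 with an estimated correlation). Epidermal and periderm genes were higher in 16 of 19 cases (camera adjusted p = 5.06e-05, 0.135 with an estimated correlation), and secreted signals of the facial epithelium were higher in 18 of 21 cases and lower in 1 (camera adjusted p = 2.38e-07, 0.135 with an estimated correlation). The signals were led by Wnt7b (3.45 ± 0.06), Wnt3 (2.91 ± 0.07) and Pdgfa (2.88 ± 0.07). Cranial mesenchyme genes were lower in 26 of 26 cases (camera adjusted p = 3.87e-11, 0.152 with an estimated correlation). Collagens and matrix genes were lower in 20 of 25 cases and higher in 4 (camera adjusted p = 6.74e-06, 0.209 with an estimated correlation). The layers also differed in genes of other cell types. Endothelial genes were lower in 17 of 17 cases (camera adjusted p = 6.76e-09, 0.152 with an estimated correlation). Erythroid genes were lower in 15 of 15 cases (camera adjusted p = 4.22e-06, 0.265 with an estimated correlation). Leukocyte genes were lower in 13 of 15 cases and higher in 1 (camera adjusted p = 0.000219, 0.209 with an estimated correlation). Skeletal muscle genes were lower in 22 of 24 cases (camera adjusted p = 5.26e-05, 0.32 with an estimated correlation). Cell cycle genes were lower in 17 of 18 cases (camera adjusted p = 0.0021, 0.426 with an estimated correlation). Cartilage and bone genes were lower in 17 of 25 cases and higher in 4 (list alone 17 and 5, camera adjusted p = 0.0117, 0.392 with an estimated correlation). DLX5/6 and HAND regulators of the lower jaw were lower in 13 of 18 cases and higher in 5 (camera adjusted p = 0.0229, 0.391 with an estimated correlation).

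The remaining lists had no call between layers. Orofacial cleft genes went both ways (11 of 24 higher and 11 lower, camera adjusted p = 0.634), with Trp63 (3.67 ± 0.07) higher in ectoderm. The dental list (11 of 19 higher and 6 lower, camera adjusted p = 0.0783) held Sostdc1 (2.60 ± 0.06), which was higher in ectoderm. Frontonasal and olfactory placode regulators (10 of 20 lower and 3 higher, camera adjusted p = 0.0696) and upper jaw regulators (12 of 20 lower and 7 higher, camera adjusted p = 0.239) went both ways too. So did signal response genes (10 of 24 lower and 9 higher, list alone 10 and 10, camera adjusted p = 0.941) and neuronal genes (13 of 17 lower and 3 higher, list alone 13 and 4, camera adjusted p = 0.115). Glial (6 of 11 lower and 4 higher, camera adjusted p = 0.8) and pharyngeal endoderm genes (4 of 8 higher and 4 lower, camera adjusted p = 0.941) were mixed. Neural tube and eye (5 of 9 higher, camera adjusted p = 0.136) and anterior Hox genes (5 of 10 higher and 1 lower, camera adjusted p = 0.296) had more members higher than lower in ectoderm. The same was true of LIN28 and early growth genes (9 of 15 higher and 4 lower, camera adjusted p = 0.433) and immediate-early genes (12 of 17 higher and 1 lower, camera adjusted p = 0.115). None of the 5 sex-linked genes passed (0 of 5 higher and 0 lower, camera adjusted p = 0.866).

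Frontonasal mesenchyme was next set against mandibular mesenchyme at E11.5 and E12.5 (6 arrays against 6). Forebrain and olfactory transcription factors were among the genes higher on the frontonasal side. Otx2 was at least 13.3-fold higher in frontonasal mesenchyme (3.73 ± 0.17, adjusted p = 2.94e-19) and Fezf1 10-fold higher (3.32 ± 0.13). Sult1e1, an estrogen sulfotransferase, was at least 21.4-fold higher (4.42 ± 0.11, probe set 10531111), and the tight-junction gene Cldn6 (3.44 ± 0.17), Fstl5 (3.38 ± 0.12) and Tfap2b (3.38 ± 0.13) were higher too. The cardiac actin gene Actc1 was 35.1-fold lower (-5.13 ± 0.25, probe set 10485982, adjusted p = 1.44e-18). Gpr50 was at least 26.1-fold lower (-4.71 ± 0.26). The smooth muscle actin Acta2 (-3.84 ± 0.13), the imprinted gene Zim1 (-3.39 ± 0.08), the antisense transcript Dlx1as (-3.10 ± 0.09) and Rtl3 (7.97-fold) were also lower. Among 2939 differing probe sets, 1712 were higher and 1227 lower in frontonasal mesenchyme, and at least 2-fold 209 and 177.

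Placode regulators were higher in 16 of 20 cases and lower in 1 (list alone 17 and 1, camera adjusted p = 3.45e-15, 0.000859 with an estimated correlation). Among them were Sox2 (3.30 ± 0.18), Lhx2 (2.82 ± 0.14) and Aldh1a3 (2.39 ± 0.11). In the same frontonasal samples epithelial genes were higher in 28 of 31 cases (camera adjusted p = 3e-25, 0.02 with an estimated correlation). Epcam stood at 2.96 ± 0.20, Esrp1 at 2.94 ± 0.23 and Krt8 at 2.37 ± 0.08. Neuronal genes were higher in 13 of 17 cases and lower in 2 (camera adjusted p = 6.7e-09, 0.0572 with an estimated correlation), with Nhlh1 at least 8.87-fold (3.15 ± 0.18) and Neurod1 at least 6.13-fold higher (2.62 ± 0.17). Secreted signals were higher in 9 of 21 cases and lower in 1 (list alone 10 and 1, camera adjusted p = 0.0232, 0.566 with an estimated correlation). Skeletal muscle genes were lower in 23 of 24 cases and higher in 1 (camera adjusted p = 3.31e-29, 0.00276 with an estimated correlation), including Myod1 (-2.36 ± 0.13) and Myog (-2.32 ± 0.11). Lower jaw regulators were lower in 14 of 18 cases and higher in 1 (camera adjusted p = 2.94e-08, 0.02 with an estimated correlation), with Hand2 at -2.98 ± 0.17 and Barx1 at -2.10 ± 0.14. Upper jaw regulators were lower in 10 of 20 cases and higher in 5 (list alone 10 and 6, camera adjusted p = 0.00437, 0.2 with an estimated correlation). The leading ones were Dlx1 (-2.93 ± 0.10) and Lhx8 (-2.19 ± 0.20). LIN28 and early growth genes were lower in 7 of 15 cases and higher in 2 (camera adjusted p = 7.81e-05, 0.0572 with an estimated correlation). The imprinted genes Dlk1 (-2.62 ± 0.11), Peg3 (-1.39 ± 0.06) and Plagl1 (-1.26 ± 0.06) were the lowest of these. Collagens were lower in 12 of 25 cases and higher in 1 (list alone 13 and 1, camera adjusted p = 0.0012, 0.403 with an estimated correlation), and cranial mesenchyme genes were lower in 10 of 26 cases and higher in 3 (list alone 11 and 5, camera adjusted p = 0.00942, 0.621 with an estimated correlation). Anterior Hox genes were lower in 5 of 10 cases (list alone 7, camera adjusted p = 0.00753, 0.403 with an estimated correlation), and endothelial genes were lower in 3 of 17 cases (camera adjusted p = 0.0107, 0.593 with an estimated correlation).

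Maxillary against mandibular mesenchyme compares the upper and lower parts of the first arch (6 arrays against 6). Transcription factors of the lower jaw were among the genes that separated them. Pitx1 was 10.7-fold lower in maxillary mesenchyme (-3.41 ± 0.12, adjusted p = 2.51e-22) and Hand2 6.78-fold lower (-2.76 ± 0.17). Rtl3 (-3.91 ± 0.14, probe set 10606366), Gpr50 (-3.60 ± 0.26), Zim1 (-2.84 ± 0.08) and Acta2 (-2.26 ± 0.13) were lower as well. Mdga2, which encodes a cell adhesion protein, was 4.57-fold higher (2.19 ± 0.14, probe set 10400607, adjusted p = 3.15e-15). It was followed by Stmn2 (1.99 ± 0.27), Foxl2os (1.88 ± 0.11), the serotonin receptor Htr1b (1.81 ± 0.11), Tmem30b (1.81 ± 0.08) and Pappa2 (1.43 ± 0.15). The 1445 differing probe sets were 600 higher and 845 lower, and 29 and 120 at 2-fold or more.

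Lower jaw regulators were lower in 10 of 18 cases and higher in 2 (list alone 11 and 2, camera adjusted p = 1.95e-09, 0.0158 with an estimated correlation). These included Dlx6 (-1.97 ± 0.14), Gsc (-1.64 ± 0.13) and Dlx5 (-1.45 ± 0.15). Upper jaw regulators were higher in 10 of 20 cases and lower in 1 (list alone 12 and 1, camera adjusted p = 3.67e-07, 0.0158 with an estimated correlation), Foxl2 (1.36 ± 0.09) and Irx5 (1.08 ± 0.07) the most. Skeletal muscle genes were lower in 22 of 24 cases (list alone 24, camera adjusted p = 1.11e-41, 0.000531 with an estimated correlation). Cartilage and bone genes were lower in 12 of 25 cases and higher in 1 (list alone 13 and 1, camera adjusted p = 1.53e-05, 0.133 with an estimated correlation). The LIN28 list was lower in 5 of 15 cases (list alone 5 and 3, camera adjusted p = 0.000667, 0.133 with an estimated correlation). Neuronal genes were higher in 11 of 17 cases and lower in 1 (list alone 12 and 1, camera adjusted p = 2.76e-06, 0.137 with an estimated correlation). Glial and migratory crest genes were higher in 4 of 11 cases and lower in 1 (camera adjusted p = 0.00161, 0.0808 with an estimated correlation), with Fabp7 at 1.11 ± 0.20. Array weights raised the count of this comparison to 2583, of which 1333 were higher and 1250 lower.

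Frontonasal against maxillary mesenchyme covers the tissues that meet at the upper lip (6 arrays against 6). Dlx1, a homeobox gene of the first arch, was 8.66-fold lower in frontonasal mesenchyme (-3.12 ± 0.10, probe set 10472809, adjusted p = 3.19e-23). The homeobox genes Lhx8 (-2.79 ± 0.20) and Lhx6 (-2.65 ± 0.16) were lower, with Tbx15 (-2.65 ± 0.27), Mab21l2 (-2.23 ± 0.26) and Actc1 (-3.02 ± 0.25). Sult1e1 was at least 19.2-fold higher (4.26 ± 0.11), Otx2 11.8-fold (3.56 ± 0.17, adjusted p = 2.3e-18) and Fezf1 10.2-fold (3.35 ± 0.13). Fstl5 (3.32 ± 0.12), Epcam (3.04 ± 0.20) and Slc27a2 (3.02 ± 0.13) were also higher. Of 2718 differing probe sets, 1707 were higher and 1011 lower, with 213 and 72 at 2-fold or more, and with array weights the count was 4108.

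Upper jaw regulators were lower in 16 of 20 cases and higher in 3 (list alone 17 and 3, camera adjusted p = 3.4e-13, 0.000665 with an estimated correlation), and placode regulators were higher in 17 of 20 cases (list alone 17 and 1, camera adjusted p = 1.62e-16, 0.000429 with an estimated correlation). In the same frontonasal samples epithelial genes were higher in 27 of 31 cases (list alone 29, camera adjusted p = 1.4e-28, 0.0146 with an estimated correlation). Neuronal genes were higher in 10 of 17 cases and lower in 3 (list alone 12 and 3, camera adjusted p = 0.000201, 0.368 with an estimated correlation), although Nefm, a neurofilament gene, was lower (-1.77 ± 0.26). Cartilage genes were higher in 11 of 25 cases and lower in 2 (camera adjusted p = 0.0166, 0.501 with an estimated correlation), with Sox9 at 1.58 ± 0.08 and Cnmd at 1.19 ± 0.11. Skeletal muscle genes were lower in 15 of 24 cases and higher in 1 (list alone 18 and 1, camera adjusted p = 8.42e-07, 0.323 with an estimated correlation). Collagens and matrix genes were lower in 12 of 25 cases and higher in 3 (camera adjusted p = 0.00449, 0.501 with an estimated correlation). Glial genes were lower in 5 of 11 cases and higher in 1 (list alone 5 and 2, camera adjusted p = 0.0098, 0.211 with an estimated correlation). Cell cycle genes were lower in 5 of 18 cases (camera adjusted p = 0.00668, 0.617 with an estimated correlation). Cranial mesenchyme genes were lower in 8 of 26 cases and higher in 5 (camera adjusted p = 0.0257, 0.632 with an estimated correlation), with Osr1 at -1.87 ± 0.13. Endothelial genes were lower in 3 of 17 cases (camera adjusted p = 0.0431, 0.632 with an estimated correlation).

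**Figure D2:**
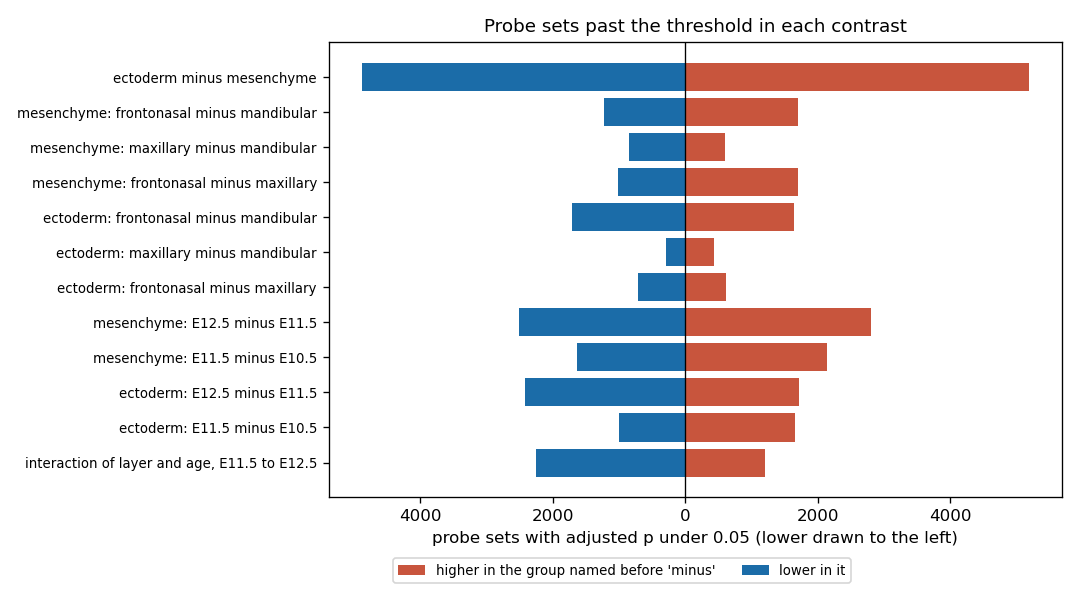
Probe sets past the threshold in each comparison, with bars to the right for those higher and to the left for those lower on the side named first. The layer comparison has the most, with 5190 higher and 4884 lower in ectoderm.

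Frontonasal against mandibular ectoderm asks the same of the surface layer (6 arrays against 6). As in the mesenchyme, the forebrain and olfactory regulators were higher on the frontonasal side. Fezf1 was 6.84-fold higher (2.77 ± 0.13, probe set 10543362, adjusted p = 3.45e-18) and Otx2 5.94-fold (2.57 ± 0.17). Aldh1a3, which makes retinoic acid (2.14 ± 0.11), the cystine transporter Slc7a11 (2.34 ± 0.11) and Stmn2 (2.22 ± 0.27) were higher. Sult1e1 was also higher (1.96 ± 0.11), but it was detected on 3 of 6 frontonasal and 0 of 6 mandibular arrays, so no least fold is given. Nearly all of the difference lay at E11.5 for Sult1e1 (3.66, against 0.25 at E12.5) and Aldh1a3 (3.89 against 0.39). Serpinb5 was 5.16-fold lower (-2.37 ± 0.13, probe set 10349108, adjusted p = 5.56e-16). Rtl3 (-2.03 ± 0.14), Acta2 (-1.72 ± 0.13), Fndc1 (-1.72 ± 0.09), the desmocollin Dsc3 (-1.71 ± 0.22) and Aldh1a7 (-1.70 ± 0.14) were also lower. Rtl3 (7.97-fold) and Acta2 (-3.84) were lower in frontonasal mesenchyme as well, and what mesenchyme left with the ectoderm adds was not tested. The count was 3348 probe sets, 1637 higher and 1711 lower (55 and 63 at 2-fold or more). This count rests on a few arrays: it was 1918 without frontonasal ectoderm E12.5 replicate 3, 1935 without frontonasal ectoderm E11.5 replicate 2 and 5054 without frontonasal ectoderm E12.5 replicate 2. It was 931 with only the groups compared, and centring each array on its median changed the split to 836 higher and 3707 lower (885 and 2840 on the same probe sets, whose median moved from 0.03 to -0.06).

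Placode regulators were higher in 18 of 20 cases and lower in 1 (camera adjusted p = 1.98e-18, 0.000163 with an estimated correlation), with Lhx2 (1.64 ± 0.14) and Pax6 (1.54 ± 0.14) among them. Neuronal genes were higher in 11 of 17 cases and lower in 1 (list alone 11 and 2, camera adjusted p = 7.37e-06, 0.252 with an estimated correlation). Neural tube and eye genes were higher in 7 of 9 cases (camera adjusted p = 0.000262, 0.175 with an estimated correlation). Glial and migratory crest genes were higher in 5 of 11 cases (list alone 6, camera adjusted p = 0.000793, 0.0891 with an estimated correlation). In that list the melanin-synthesis genes Dct (1.82 ± 0.12) and Pmel (1.27 ± 0.10) were the largest. Leukocyte genes were higher in 7 of 15 cases (list alone 8, camera adjusted p = 0.00836, 0.703 with an estimated correlation), and cartilage genes were higher in 7 of 25 cases and lower in 2 (list alone 9 and 2, camera adjusted p = 0.0265, 0.767 with an estimated correlation). Cell cycle genes were lower in 5 of 18 cases and higher in 1 (list alone 6 and 1, camera adjusted p = 0.0162, 0.767 with an estimated correlation). On the mandibular side stood the homeobox genes Pitx1 (-1.48 ± 0.12) and Nkx2-3 (-1.34 ± 0.15) and the keratin Krt15 (-1.55 ± 0.14).

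Maxillary and mandibular ectoderm, which face each other across the mouth, gave the smallest count of the prominence comparisons (6 arrays against 6). Aldh1a3 was 3.56-fold higher in maxillary ectoderm (1.83 ± 0.11, probe set 10564417, adjusted p = 1.54e-14). The WNT inhibitor Dkk4 was 2.76-fold higher (1.46 ± 0.11), and the glutamate receptor Gria2 (1.74 ± 0.13), Tbx15 (1.67 ± 0.27), Slc7a11 (1.41 ± 0.11) and Lrrn1 (1.23 ± 0.22) were higher. Rtl3 was 4.63-fold lower (-2.21 ± 0.14, probe set 10606366, adjusted p = 3.03e-14). It was lower in maxillary mesenchyme as well (-3.91), and what mesenchyme left with the ectoderm adds was not tested. Serpinb5 (-1.64 ± 0.13), the homeobox gene Tlx1 (-1.60 ± 0.12), the desmosomal cadherins Dsc3 (-1.50 ± 0.22) and Dsg1a (-1.44 ± 0.19), and Gsdmc (-1.42 ± 0.09) were lower. In total 730 probe sets differed, 439 higher and 291 lower (19 and 20 at 2-fold or more). With array weights there were 1202, and after median centring the split was 296 higher and 349 lower. Lrrn1 was not called with only the groups compared (adjusted p = 0.0839, against 6.07e-06 to 0.00215 in the other alternatives).

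Response genes of hedgehog, FGF, WNT and BMP signalling were higher in 13 of 24 cases (list alone 15 and 2, camera adjusted p = 6.33e-10, 0.0131 with an estimated correlation), with Spry4 at 0.55 ± 0.09. Upper jaw regulators were higher in 9 of 20 cases (list alone 11, camera adjusted p = 4.99e-09, 0.0128 with an estimated correlation), with Osr2 at 1.11 ± 0.13 and Cyp26a1 at 1.02 ± 0.15. Dental genes were higher in 7 of 19 cases and lower in 3 (list alone 9 and 3, camera adjusted p = 0.0113, 0.0317 with an estimated correlation). Placode regulators were higher in 6 of 20 cases (list alone 7, camera adjusted p = 2.78e-05, 0.0641 with an estimated correlation). Secreted signals were higher in 4 of 21 cases (list alone 6, camera adjusted p = 0.0413, 0.603 with an estimated correlation). In the same maxillary samples cranial mesenchyme genes were higher in 7 of 26 cases (list alone 13, camera adjusted p = 2.29e-05, 0.372 with an estimated correlation). Collagens were higher in 5 of 25 cases (list alone 8, camera adjusted p = 0.000596, 0.372 with an estimated correlation), and epithelial genes were lower in 2 of 31 cases (camera adjusted p = 0.0113, 0.657 with an estimated correlation). Pharyngeal endoderm genes were lower in 3 of 8 cases and higher in 1 (list alone 4 and 1, camera adjusted p = 0.0113, 0.265 with an estimated correlation), among them the regulators Foxa1 (-1.17 ± 0.12) and Foxa2 (-0.65 ± 0.11). Lower jaw regulators were lower in 4 of 18 cases and higher in 1 (list alone 7 and 3, camera adjusted p = 0.0312, 0.434 with an estimated correlation). Anterior Hox genes were lower in 2 of 10 cases (list alone 3, camera adjusted p = 0.00542, 0.372 with an estimated correlation), and epidermal genes were lower in 2 of 19 cases (list alone 3, camera adjusted p = 0.0229, 0.372 with an estimated correlation).

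Frontonasal against maxillary ectoderm completes the set (6 arrays against 6). Fezf1 (6.21-fold, 2.63 ± 0.13, probe set 10543362, adjusted p = 7.35e-17) and Otx2 (5.76-fold, 2.52 ± 0.17) were higher in frontonasal ectoderm. Sult1e1 was higher too (1.97 ± 0.11, with 3.72 at E11.5 and 0.22 at E12.5), but it was detected on 3 of 6 frontonasal and 0 of 6 maxillary arrays. Dct (1.62 ± 0.12, with 0.34 at E11.5 and 2.90 at E12.5), the homeobox gene Alx1 (1.55 ± 0.21) and the neuronal membrane gene Gpm6a (1.52 ± 0.13) were higher. Tbx15, a T-box transcription factor, was 6.67-fold lower (-2.74 ± 0.27, probe set 10494672, adjusted p = 3.41e-09). Mab21l2 (-1.80 ± 0.26), Lhx8 (-1.75 ± 0.20), the matrix gene Postn (-1.62 ± 0.18), Chl1 (-1.45 ± 0.13) and Tbx18 (-1.42 ± 0.17) were lower too. Tbx15 (-2.65), Mab21l2 (-2.23) and Lhx8 (-2.79) were also lower in frontonasal than in maxillary mesenchyme. How much mesenchyme left with the ectoderm adds to these ectoderm differences was not tested. The count was 1337, 624 higher and 713 lower (28 and 25 at 2-fold or more). Of 100 splits of the arrays 10 gave as many, so chance was not excluded for this count. It was 367 with only the groups compared, and the split after median centring was 428 higher and 996 lower.

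Placode regulators were higher in 14 of 20 cases and lower in 1 (list alone 17 and 1, camera adjusted p = 3.92e-16, 0.000445 with an estimated correlation), and upper jaw regulators were lower in 11 of 20 cases and higher in 1 (list alone 12 and 1, camera adjusted p = 3.89e-06, 0.0477 with an estimated correlation). Neuronal genes were higher in 10 of 17 cases (list alone 10 and 1, camera adjusted p = 3.86e-06, 0.171 with an estimated correlation). Glial genes were higher in 4 of 11 cases (list alone 5 and 1, camera adjusted p = 0.000467, 0.0589 with an estimated correlation). Neural tube and eye genes were higher in 4 of 9 cases (list alone 8, camera adjusted p = 1.41e-05, 0.0638 with an estimated correlation). Leukocyte genes were higher in 6 of 15 cases (list alone 9 and 1, camera adjusted p = 0.00148, 0.321 with an estimated correlation), and erythroid genes were higher in 3 of 15 cases (list alone 4, camera adjusted p = 0.000467, 0.478 with an estimated correlation). Collagens were lower in 9 of 25 cases and higher in 1 (list alone 13 and 1, camera adjusted p = 1.14e-05, 0.234 with an estimated correlation). Signal response genes were lower in 6 of 24 cases and higher in 3 (list alone 10 and 4, camera adjusted p = 0.0156, 0.41 with an estimated correlation), among them Ptch1 (-0.82 ± 0.08) and Gli1 (-0.72 ± 0.08). Small shifts were called without any gene passing. Endothelial genes leaned to the frontonasal side (camera adjusted p = 0.0253, 0.683 with an estimated correlation) and cell cycle genes to the maxillary side (camera adjusted p = 0.00795, 0.662 with an estimated correlation).

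From E11.5 to E12.5 the mesenchyme was compared within each prominence (9 arrays against 9). Extracellular matrix genes gave the largest rises. Aspn, which encodes a small proteoglycan that binds collagen, rose 12.4-fold (3.64 ± 0.12, probe set 10405047, adjusted p = 4.34e-23). Its relatives Dcn (2.75 ± 0.12) and Ogn (2.59 ± 0.11) rose with Anxa1 (2.57 ± 0.14), Egfl6 (2.51 ± 0.09) and Chodl (2.32 ± 0.14). The embryonic globin Hbb-bh1 fell 5.57-fold (-2.48 ± 0.22, probe set 10566268, adjusted p = 2.8e-11). The red cell genes Ahsp (-1.65 ± 0.15) and Hemgn (-1.39 ± 0.10), the metallothionein Mt2 (-1.60 ± 0.10) and the carbonic anhydrase Car14 (-1.55 ± 0.08) fell with it. Of 5314 changed probe sets 2805 rose and 2509 fell (120 and 36 at 2-fold or more). With a detection filter 8059 changed, and after median centring the split was 2148 up and 3889 down (2157 and 2949 on the same probe sets).

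All 25 collagen and matrix genes rose (camera adjusted p = 2.76e-20, 0.0148 with an estimated correlation), with Col12a1 at 1.77 ± 0.07 and Col1a1 at 1.64 ± 0.13. Cartilage and bone genes rose in 14 of 25 cases and fell in 1 (list alone 15 and 1, camera adjusted p = 0.000246, 0.303 with an estimated correlation). Among them were the osteoblast genes Alpl (1.54 ± 0.09), Sp7 (1.45 ± 0.10) and Runx2 (1.06 ± 0.08). Skeletal muscle genes rose in 20 of 24 cases (list alone 21 and 1, camera adjusted p = 5.28e-07, 0.303 with an estimated correlation), led by Myh3 (1.20 ± 0.09). Orofacial cleft genes rose in 13 of 24 cases and fell in 2 (list alone 15 and 2, camera adjusted p = 0.0179, 0.308 with an estimated correlation). Epithelial genes rose in 13 of 31 cases (list alone 14, camera adjusted p = 0.0179, 0.762 with an estimated correlation), with Krt5 at 2.04 ± 0.18 and Krt14 at 1.60 ± 0.18. Both keratins also rose in ectoderm, and how much of the rise is ectoderm left with the mesenchyme was not tested. In maxillary mesenchyme, replicate 2 held more Krt14 than replicates 1 and 3 at E11.5 (6.97 against 5.39 and 5.18) and at E12.5 (8.05 against 6.21 and 6.03). Cell cycle genes fell in 18 of 18 cases (camera adjusted p = 4.88e-12, 0.172 with an estimated correlation), with Rrm2 at -0.66 ± 0.05. Erythroid genes fell in 12 of 15 cases (camera adjusted p = 1.01e-08, 0.303 with an estimated correlation), and LIN28 and early growth genes fell in 7 of 15 cases and rose in 3 (list alone 9 and 3, camera adjusted p = 0.0179, 0.358 with an estimated correlation). The last were led by Lin28b (-1.32 ± 0.07), Mycn (-0.83 ± 0.07) and Sall4 (-0.81 ± 0.09).

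From E10.5 to E11.5 the mesenchyme was compared in the frontonasal and mandibular prominences (6 arrays against 6). Aldh1a2 rose 4.85-fold (2.28 ± 0.22, probe set 10586865, adjusted p = 4.12e-10). The opioid precursor Penk (2.23 ± 0.09), the matrix gene Postn (2.20 ± 0.18), Tbx15 (2.12 ± 0.27), AW551984 (2.03 ± 0.20) and Pgm5 (2.01 ± 0.13) rose as well. Igdcc3, an immunoglobulin-family gene of early embryos, fell 5.78-fold (-2.53 ± 0.11, probe set 10586331, adjusted p = 6.81e-19). Its relative Prtg (-1.54 ± 0.08), the stem cell regulators Sall4 (-1.38 ± 0.11) and Lin28b (-1.37 ± 0.08), and Mogat2 (-1.29 ± 0.12) fell. Of 3776 changed probe sets 2141 rose and 1635 fell (116 and 36 at 2-fold or more). Collagens rose in 21 of 25 cases (list alone 21 and 1, camera adjusted p = 1.57e-11, 0.0899 with an estimated correlation), with Tnc at 2.00 ± 0.14. Dental genes rose in 8 of 19 cases and fell in 1 (camera adjusted p = 0.00591, 0.0459 with an estimated correlation), among them Bmp2 (1.44 ± 0.13), Fst (1.39 ± 0.08) and Pax9 (1.28 ± 0.13). Orofacial cleft genes rose in 11 of 24 cases (list alone 12, camera adjusted p = 0.00557, 0.204 with an estimated correlation), and upper jaw regulators rose in 8 of 20 cases and fell in 2 (list alone 9 and 2, camera adjusted p = 0.022, 0.474 with an estimated correlation). Cranial mesenchyme genes rose in 14 of 26 cases (camera adjusted p = 0.000359, 0.541 with an estimated correlation). Skeletal muscle genes rose in 10 of 24 cases and fell in 1 (camera adjusted p = 0.00936, 0.722 with an estimated correlation). Erythroid genes rose in 12 of 15 cases (camera adjusted p = 0.000303, 0.487 with an estimated correlation). Glial genes rose in 6 of 11 cases (list alone 8, camera adjusted p = 0.0127, 0.204 with an estimated correlation). The LIN28 list fell in 9 of 15 cases and rose in 3 (list alone 9 and 4, camera adjusted p = 0.000745, 0.204 with an estimated correlation), and cell cycle genes fell in 10 of 18 cases (list alone 11, camera adjusted p = 0.000303, 0.487 with an estimated correlation).

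From E11.5 to E12.5 the ectoderm was compared within each prominence (9 arrays against 9). The heat shock gene Hspa1a rose 13.3-fold (3.74 ± 0.46, probe set 10450369, adjusted p = 3.08e-08). The desmosomal cadherins Dsg1a (2.45 ± 0.15) and Dsc3 (1.70 ± 0.18) rose with Dcn (2.15 ± 0.12), Anxa1 (1.92 ± 0.14) and Lmo1 (1.74 ± 0.12). Hbb-bh1 fell 8.16-fold (-3.03 ± 0.22, probe set 10566268, adjusted p = 2.77e-13). The matrix linker Hapln1 (-2.70 ± 0.09), Maob (-2.12 ± 0.14), Fndc3c1 (-1.99 ± 0.08), Car14 (-1.96 ± 0.08) and Mecom (-1.73 ± 0.15) fell too. Of 4152 changed probe sets 1726 rose and 2426 fell (58 and 79 at 2-fold or more). Without the frontonasal groups the count was 2694.

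The largest changes of the epithelial list went both ways. Krt5 (1.64 ± 0.18), Krt14 (1.52 ± 0.18) and Krt15 (1.39 ± 0.11), which belong to stratified epithelium, rose. Krt8 (-1.57 ± 0.07) and Krt18 (-1.30 ± 0.11), which belong to simple epithelium, fell with the tight-junction gene Cldn7 (-1.28 ± 0.11). The epithelial list as a whole went both ways and was not called (8 of 31 rose and 8 fell, camera adjusted p = 0.473). Epidermal genes rose (10 of 19 rose, list alone 12, camera adjusted p = 2.43e-06, 0.0718 with an estimated correlation), with Krt17 at 1.69 ± 0.12. Placode regulators fell in 14 of 20 cases (camera adjusted p = 9.73e-06, 0.0764 with an estimated correlation), with Aldh1a3 (-1.55 ± 0.09) and Sox2 (-1.34 ± 0.15) among them. Neuronal genes fell in 14 of 17 cases and rose in 1 (list alone 15 and 1, camera adjusted p = 0.000114, 0.316 with an estimated correlation), with Elavl4 at -1.33 ± 0.13. These averages include frontonasal tissue, where the share of ectoderm Krt8 signal found in the mesenchyme went from 28.9% at E11.5 to 255% at E12.5. The share is taken above the signal of mandibular and maxillary mesenchyme, and it also grows as the ectoderm signal falls. With the frontonasal groups left out, Krt8, Krt18, Cldn7, Aldh1a3, Sox2 and Elavl4 still fell and were still called. Their falls were therefore not confined to frontonasal tissue. How much nasal epithelium kept with the mesenchyme adds to the size of these falls, or to those of the placode and neuronal lists, was not tested. Collagens rose in 15 of 25 cases and fell in 4 (list alone 16 and 4, camera adjusted p = 1.51e-05, 0.316 with an estimated correlation), and glial genes rose in 4 of 11 cases and fell in 1 (list alone 5 and 1, camera adjusted p = 0.0129, 0.242 with an estimated correlation). Erythroid genes fell in 9 of 15 cases (list alone 13, camera adjusted p = 0.000171, 0.564 with an estimated correlation). Cell cycle genes fell in 12 of 18 cases (list alone 13, camera adjusted p = 0.00112, 0.638 with an estimated correlation). The LIN28 list fell in 9 of 15 cases and rose in 1 (list alone 10 and 1, camera adjusted p = 0.000841, 0.242 with an estimated correlation). Secreted signals were not called as a list (8 of 21 rose and 5 fell, list alone 9 and 5, camera adjusted p = 0.391). Among them Fgf8 (-1.24 ± 0.09) and Bmp4 (-1.01 ± 0.08) fell and Wnt7a (1.10 ± 0.08) rose.

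From E10.5 to E11.5 only mandibular ectoderm could be compared (3 arrays against 3). Anxa1 rose 15.6-fold (3.96 ± 0.24, probe set 10466606, adjusted p = 8.93e-15) and Gabrp 10.1-fold (3.34 ± 0.21). The mesenchymal transcription factors Prrx1 (3.13 ± 0.40) and Twist1 (3.11 ± 0.34), Mab21l2 (3.30 ± 0.37) and the embryonic globin Hbb-y (3.02 ± 0.30) rose in the same samples. Igdcc3 fell 4.83-fold (-2.27 ± 0.16, probe set 10586331, adjusted p = 2.41e-13), with Lin28a (-2.22 ± 0.14), Pmp22 (-2.03 ± 0.16), Sall4 (-1.60 ± 0.15), Prtg (-1.59 ± 0.11) and Smoc1 (-1.57 ± 0.13). Of 2662 changed probe sets 1656 rose and 1006 fell (222 and 61 at 2-fold or more). Cranial mesenchyme genes rose in 20 of 26 cases (list alone 23, camera adjusted p = 3.23e-12, 0.129 with an estimated correlation). Collagens rose in 14 of 25 cases and fell in 1 (list alone 15 and 2, camera adjusted p = 5.2e-07, 0.179 with an estimated correlation). Endothelial genes rose in 9 of 17 cases (camera adjusted p = 0.000382, 0.451 with an estimated correlation), and erythroid genes rose in 9 of 15 cases (list alone 11, camera adjusted p = 8.5e-06, 0.306 with an estimated correlation). Epidermal genes rose in 8 of 19 cases (list alone 9, camera adjusted p = 0.0134, 0.306 with an estimated correlation), and Krt5 (2.87 ± 0.31) and Krt15 (2.79 ± 0.19) rose among epithelial genes. Upper jaw regulators rose in 9 of 20 cases and fell in 1 (list alone 14 and 1, camera adjusted p = 3.97e-05, 0.0832 with an estimated correlation). Lower jaw regulators rose in 8 of 18 cases and fell in 1 (list alone 9 and 1, camera adjusted p = 0.041, 0.508 with an estimated correlation). Orofacial cleft genes rose in 11 of 24 cases and fell in 1 (list alone 18 and 1, camera adjusted p = 2.73e-05, 0.0832 with an estimated correlation). Immediate-early genes rose in 4 of 17 cases (list alone 6, camera adjusted p = 0.041, 0.884 with an estimated correlation). The LIN28 list fell in 6 of 15 cases and rose in 1 (list alone 7 and 1, camera adjusted p = 3.75e-05, 0.0832 with an estimated correlation), and cell cycle genes fell in 2 of 18 cases (camera adjusted p = 0.0133, 0.708 with an estimated correlation).

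**Figure D3:**
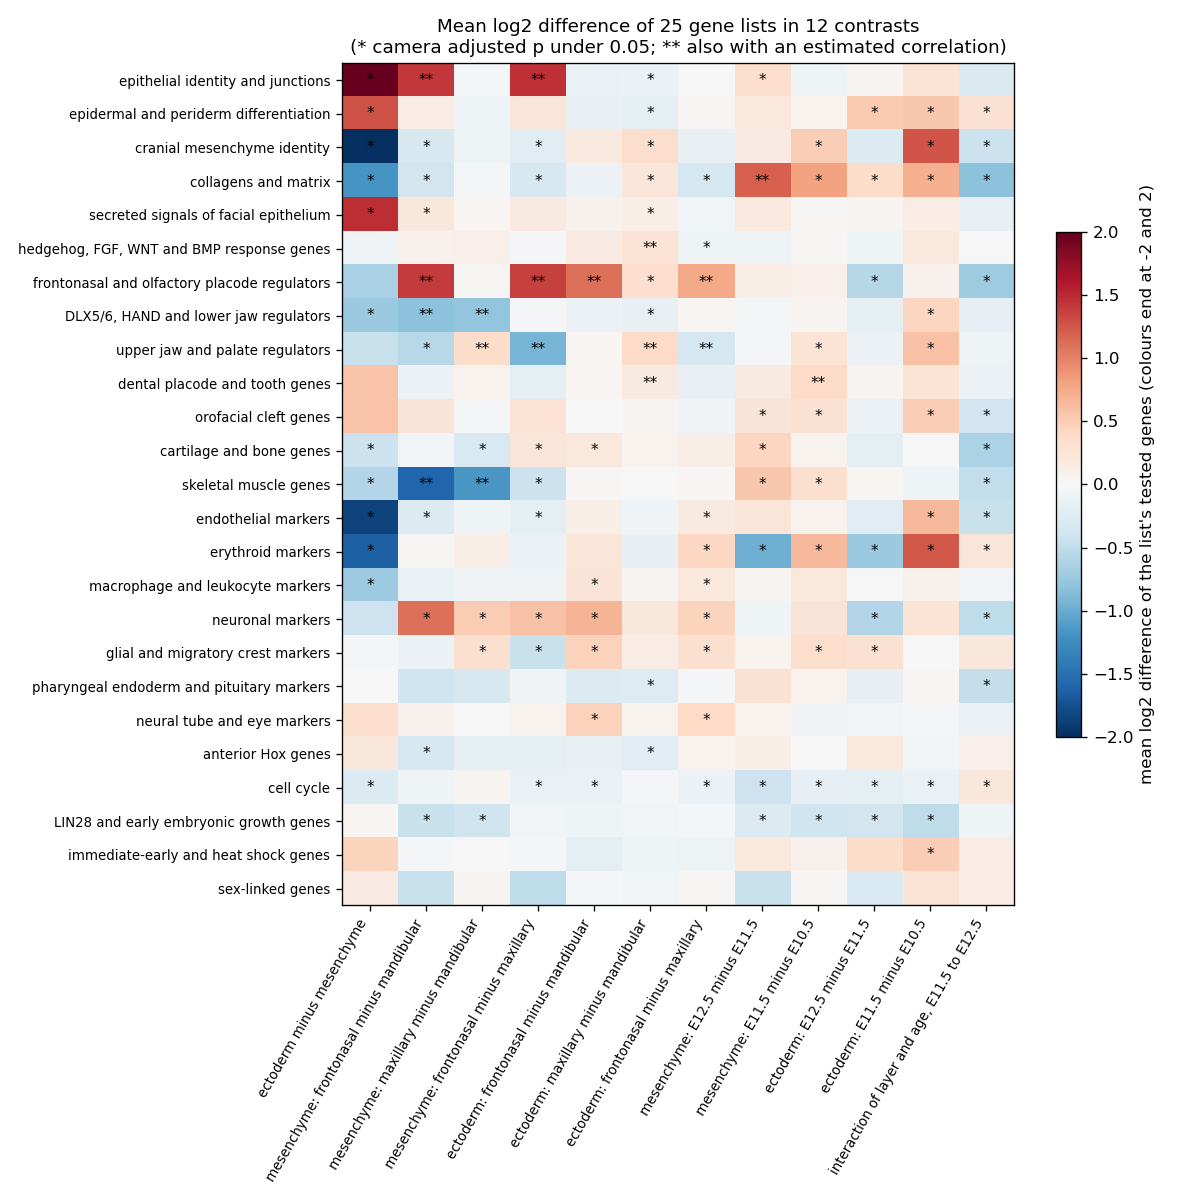
Mean log2 difference of each of the 25 gene lists in each of the 12 comparisons, with marks where the list was called with the preset correlation and where it was also called with an estimated one. Means run from -2.04 to 3.00, and 121 of 300 pairs were called, 18 of them with both.

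Whether the layers changed differently from E11.5 to E12.5 was tested as an interaction, ectoderm change minus mesenchyme change (9 arrays against 9 in each layer). Matrix genes rose more in the mesenchyme. Aspn differed by -3.43 ± 0.17, Egfl6 by -2.39 ± 0.12 and Ogn by -2.34 ± 0.16. Of 3459 probe sets called 1210 moved higher in ectoderm and 2249 moved lower (30 and 239 at 2-fold or more). Median centring changed the split to 1606 and 1834, and to 1339 and 1818 on the same probe sets. In ectoderm relative to mesenchyme, collagens moved lower in 24 of 25 cases (camera adjusted p = 3.23e-13, 0.0923 with an estimated correlation). Placode regulators moved lower in 13 of 20 cases (list alone 17, camera adjusted p = 9.26e-06, 0.0923 with an estimated correlation). Nasal epithelium kept with the frontonasal mesenchyme could add to this shift of the placode list, and its part was not tested. Cartilage genes moved lower in 16 of 25 cases (list alone 17, camera adjusted p = 4.28e-07, 0.104 with an estimated correlation). Skeletal muscle genes moved lower in 17 of 24 cases (list alone 18 and 1, camera adjusted p = 1.14e-05, 0.317 with an estimated correlation). Orofacial cleft genes moved lower in 13 of 24 cases (camera adjusted p = 0.000909, 0.128 with an estimated correlation). Endothelial genes moved lower in 10 of 17 cases (list alone 11, camera adjusted p = 0.00472, 0.595 with an estimated correlation). Neuronal genes moved lower in 10 of 17 cases and higher in 1 (camera adjusted p = 0.0248, 0.595 with an estimated correlation). Pharyngeal endoderm genes moved lower in 4 of 8 cases (camera adjusted p = 0.0315, 0.317 with an estimated correlation). Cranial mesenchyme genes moved lower in 9 of 26 cases and higher in 3 (list alone 12 and 3, camera adjusted p = 0.0248, 0.775 with an estimated correlation). Epidermal genes moved higher in 7 of 19 cases and lower in 1 (list alone 8 and 1, camera adjusted p = 0.000909, 0.168 with an estimated correlation). Cell cycle genes moved higher in 9 of 18 cases (list alone 15, camera adjusted p = 4.18e-06, 0.317 with an estimated correlation). Erythroid genes moved higher in 8 of 15 cases (list alone 8 and 2, camera adjusted p = 0.0052, 0.595 with an estimated correlation). The layer difference also depended on the prominence for 2833 probe sets, 505 of them by at least 2-fold between a pair of prominences (6 arrays per layer and prominence).

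Many prominence and age differences had the same direction in both layers. Frontonasal against mandibular, 520 probe sets were higher in both layers against 194 for independent lists, and 295 were lower in both against 145. Maxillary against mandibular, the numbers were 113 against 18.2 and 78 against 17.0, and frontonasal against maxillary they were 357 against 73.6 and 232 against 49.8. From E11.5 to E12.5, 832 rose in both layers against 334 and 1065 fell in both against 421. From E10.5 to E11.5, 928 rose in both against 245 and 435 fell in both against 114, with the ectoderm measured in the mandibular prominence alone. Opposite directions, higher in ectoderm and lower in mesenchyme first, were found for 127 and 178 probe sets frontonasal against mandibular (139 and 202 for independent lists). They were 49 and 19 (25.6 and 12.1) for maxillary against mandibular, both above the value for independent lists, and 17 and 99 (43.6 and 84.1) for frontonasal against maxillary. With age they were 50 and 393 (299 and 470) in the later interval and 20 and 70 (187 and 149) in the earlier one. No correction was made for tissue of one layer left with the other, so a shared direction is not evidence of a change in both.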

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

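The tests of epithelial signal in frontonasal mesenchyme and of mesenchymal signal in mandibular ectoderm were chosen only after the results were seen, and the tests of the arrays that stand apart were written before.

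The change from E11.5 to E12.5 differed between the layers for 3459 probe sets, tested as an interaction. For this count the ages were shuffled within each layer and prominence. In 100 such splits the highest other count was 910 and 1 split, the real one, reached the real count. These splits also break up the change with age that both layers share, so they cannot exclude chance for the interaction itself. Aspn differed by -3.43 (ectoderm 0.20, mesenchyme 3.64), Egfl6 by -2.39 (ectoderm 0.12, mesenchyme 2.51) and Ogn by -2.34 (ectoderm 0.25, mesenchyme 2.59), so these matrix genes rose in the mesenchyme, and their ectoderm changes did not pass. Hapln1 differed by -3.06 (ectoderm -2.70, mesenchyme 0.36) and Adamts9 by -2.34 (ectoderm -1.51, mesenchyme 0.83). Hspa1a differed by 2.29 (ectoderm 3.74, mesenchyme 1.45, adjusted p = 0.00732).

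The difference between the layers depended on the prominence for 2833 probe sets. Here the prominences were shuffled within each layer and age. The highest other count of 100 splits was 665, and 1 split, the real one, reached the real count. Prominence differences shared by both layers are lost in such splits too, so chance was not excluded for the interaction itself. Sox2, a regulator of placodes, gave the largest frontonasal minus mandibular value, -4.34, with ectoderm minus mesenchyme at -0.59 in frontonasal, 3.74 in mandibular and 2.41 in maxillary tissue. Cldn6 (-3.31) and Esrp1 (-3.25), both epithelial genes, had smaller layer differences in frontonasal (1.11 and 1.93) than in mandibular tissue (4.42 and 5.18). Actc1 (4.08) and Gpr50 (3.61) had layer differences of -3.94 and -3.53 in mandibular, -1.98 and -0.72 in maxillary, and 0.13 and 0.08 in frontonasal tissue. Dlx1 gave 3.05 for frontonasal minus maxillary, with layer differences of 2.41 in frontonasal, -0.50 in mandibular and -0.64 in maxillary tissue.

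Epithelial genes were high in frontonasal mesenchyme. Surface ectoderm left on the mesenchyme would bring every epithelial gene at the same share of its ectoderm signal. The share is the frontonasal mesenchyme signal over the frontonasal ectoderm signal, on the linear scale. The mean signal of mandibular and maxillary mesenchyme was first subtracted from both. The 95% intervals of 20 of the 31 list members leave out the list's median share of 13.7% at E11.5, which argues against it as the single source: Krt14 stood at 3.70% and Krt15 at 0.423%, but Krt8 at 28.9% and Epcam at 41.8%, and at E12.5 Krt8 reached 255% and Krt18 204%. The nasal pits, whose olfactory epithelium lies within this prominence, may have stayed with the mesenchyme: the placode regulators higher in frontonasal ectoderm at E11.5 were a median of 1.99 log2 higher in frontonasal mesenchyme than in frontonasal ectoderm at E12.5. Expression of these genes by the mesenchyme itself was not tested and stays open.

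Mesenchymal and blood genes rose in mandibular ectoderm from E10.5 to E11.5. Of 136 probe sets at least 2 log2 higher in maxillary mesenchyme than in maxillary ectoderm at E11.5, 131 were higher in E11.5 than in E10.5 mandibular ectoderm (12 of 12 where the bound is 3), and so were 90.5% of the 21 among the 136 that had not risen in mandibular mesenchyme, with a median rise of 1.05, which is consistent with mesenchyme carried over in the peeled ectoderm. A single share of mesenchyme was tested on 86 probe sets at least 3 log2 higher in E11.5 mesenchyme than in E10.5 ectoderm. The median share was 14.8% (17.5% for cranial mesenchyme, 19.1% for collagens, 14.6% for endothelial and 25.7% for erythroid genes), and shares ran from 0.79% to 47.1%. Of the 95% intervals, 33.7% leave out the median share, more than would be missed if 1 share held, and the others include it. The 33.7% lies between the bounds set for either answer. The intervals nevertheless argue against 1 share as the account of all 86 probe sets. They do not exclude carried-over mesenchyme as 1 of several sources. In E11.5 mandibular ectoderm replicate 1 lay below replicates 2 and 3 in the mean log2 signal of cranial mesenchyme (7.05 against 7.79 and 8.01), endothelial (5.68 against 6.38 and 6.36) and erythroid genes (6.34 against 7.28 and 7.50) at once, so the size of the rise depends on the replicate. A true change of these genes in ectoderm with age stays open, as untested.

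The 3 arrays farthest from their replicates are frontonasal ectoderm E12.5 replicate 3 (2.57 times the median distance), frontonasal ectoderm E11.5 replicate 2 (1.90) and maxillary mesenchyme E12.5 replicate 1 (1.60). A component shared within groups holds 34.7% of the variance between replicates. Over tested probe sets, which are not independent replicates, its rho with the layer difference was 0.0804, which argues against carry-over of the other layer as the source of the component. Extra mesenchyme in the 2 ectoderm arrays is not ruled out. Each was the highest of its replicates in cranial mesenchyme genes (7.97 against 7.67 and 7.04 at E11.5, 7.63 against 7.19 and 7.07 at E12.5). The same held for endothelial and erythroid genes, but not for collagens at E12.5 (7.79 against 7.85 and 7.77). The component's score had r = -0.32 (permutation p = 0.0307, two-sided) and rho = -0.41 (permutation p = 0.0187) with the number of detected probe sets over 45 arrays, and r = -0.29 without the 2 farthest, and over probe sets its rho with brightness was -0.50. Signal over background and brightness therefore cannot be told apart from other sources of this component, since both values fall between the bounds set for either answer, and no biological explanation was tested. In E12.5 ectoderm, replicate 3 had the only positive score in frontonasal (43.4), mandibular (12.6) and maxillary tissue (15.7), and the fewest detected probe sets in each. The labels give no batch to set beside this.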

How the results depend on the processing

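Leaving out the 3 arrays that stand apart, leaving out the frontonasal groups and centring on the same probe sets were chosen only after the results were seen.

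The direction of each named gene held in every alternative run, and so did its call, with the exception of Lrrn1 in maxillary minus mandibular ectoderm, whose difference of 1.23 had an adjusted p of 0.0839 with only the groups compared. Most counts stayed within 1.5 times their value. Those that did not are the following, and the cause was not tested unless it is named.

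Without the variance filter 11505 probe sets differed by age in the three-factor model, and with the detection filter 11566, since more probe sets were tested. The detection filter also gave 8059 for mesenchyme E12.5 minus E11.5. Array weights gave 2583 for maxillary minus mandibular mesenchyme, 4108 for frontonasal minus maxillary mesenchyme and 1202 for maxillary minus mandibular ectoderm. With only the groups compared, frontonasal minus mandibular ectoderm gave 931 and frontonasal minus maxillary ectoderm 367. Leaving out the 3 arrays gave 1705 for frontonasal minus mandibular ectoderm, and leaving out the frontonasal groups gave 2694 for ectoderm E12.5 minus E11.5. An estimated correlation gave 18 list calls in place of 121, since it widens the error of correlated genes.

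Leaving out each array in turn moved frontonasal minus mandibular ectoderm from 1918, without frontonasal ectoderm E12.5 replicate 3, to 5054, without frontonasal ectoderm E12.5 replicate 2, and gave 1935 without frontonasal ectoderm E11.5 replicate 2. In every other comparison the counts stayed within 1.5 times the full count. The range was 9861 to 10406 for the layer, 2693 to 2788 for frontonasal minus mandibular mesenchyme, 1257 to 1456 for maxillary minus mandibular mesenchyme and 2394 to 2712 for frontonasal minus maxillary mesenchyme. It was 579 to 848 for maxillary minus mandibular ectoderm and 977 to 1807 for frontonasal minus maxillary ectoderm. For the ages it was 4962 to 5328 and 3344 to 3648 in mesenchyme, and 3712 to 4682 and 1894 to 2342 in ectoderm, later interval first. The interactions ranged from 3223 to 4338 with age and from 2506 to 3301 with prominence, and the factors from 9547 to 10041 for layer, 2846 to 3396 for prominence and 6983 to 7524 for age.

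A block for the replicate number left 10077 for the layer, and within age and prominence as a random block 10110. With the replicate block the mesenchyme prominence counts were 2966, 1446 and 2730, the ectoderm ones 3339, 737 and 1343, and the age counts 5308, 3787, 4176 and 2675. The interaction counts with the replicate block were 3461 with age and 2888 with prominence.

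Median centring, after which the filter on variance picks other probe sets, moved the split between higher and lower by more than 10 points in frontonasal minus mandibular ectoderm (836 and 3707), maxillary minus mandibular ectoderm (296 and 349), frontonasal minus maxillary ectoderm (428 and 996), mesenchyme E12.5 minus E11.5 (2148 and 3889) and the interaction with age (1606 and 1834). On the same probe sets, in that order, centring gave 885 and 2840, 300 and 348, 435 and 907, 2157 and 2949, and 1339 and 1818, the last within 10 points. Array weights did so in maxillary minus mandibular mesenchyme (1333 and 1250). Signal over background limits weak genes: between 76.0% and 91.7% of probe sets were detected on an array.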

Other observations

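The test of every grouping in this part was planned apart from the splits with arrays or groups left out, which were chosen after the results were seen, and the genes in the first paragraph were chosen after their values were seen.

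Compared with E11.5, the pigment cell genes Dct and Pmel, for which no separate list was tested, were higher in frontonasal ectoderm at E12.5. Dct, which acts in melanin synthesis, had a log2 signal of 8.20 ± 0.30 there (SD, n = 3) against 4.84 ± 0.33 a day earlier, and Pmel, a melanosome gene, 8.03 ± 0.34 against 5.57 ± 0.17. At E12.5 maxillary ectoderm held Dct at 5.31 ± 0.03 and mandibular ectoderm at 4.98 ± 0.41. The endoderm regulator Foxa1 was at 7.72 ± 0.20 in mandibular ectoderm at E11.5 and at 5.82 ± 0.05 at E12.5, with 5.94 ± 0.27 in frontonasal and 5.58 ± 0.01 in maxillary ectoderm at E11.5. The imprinted growth gene Dlk1 stood at 11.31 ± 0.06 in mandibular, 8.90 ± 0.27 in maxillary and 8.42 ± 0.13 in frontonasal mesenchyme at E12.5. Sox2 was at 9.16 ± 0.40 in frontonasal ectoderm at E11.5 and 6.71 ± 0.51 at E12.5, while frontonasal mesenchyme held it at 8.49 ± 0.16 and 8.57 ± 0.14.

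Other splits of the arrays into groups of the same sizes were fitted in the same way, 100 for each count unless stated, the real split included. For the factors, 1 split reached the real count for layer (9723, highest other 6219), prominence (3209, highest other 4) and age (7212, highest other 930), so chance was excluded. The same number, 1 of 100, was found for ectoderm minus mesenchyme (10074, highest other 3175), and in mesenchyme for frontonasal minus mandibular (2939, highest other 1660), maxillary minus mandibular (1445, highest other 704) and frontonasal minus maxillary (2718, highest other 1565). In ectoderm it held for frontonasal minus mandibular (3348, highest other 2953) and maxillary minus mandibular (730, highest other 327). The count for frontonasal minus mandibular ectoderm rests on a few arrays, but 1 of 100 splits also reached it without frontonasal ectoderm E12.5 replicate 3 (1918, highest other 1549) and without frontonasal ectoderm E11.5 replicate 2 (1935, highest other 1255). The same was found without the 3 arrays that stand apart (1705, highest other 609) and with only the groups compared (931, highest other 189). One split, the real one, also gave the highest count for mesenchyme E12.5 minus E11.5 (5314, highest other 3868), mesenchyme E11.5 minus E10.5 (3776, highest other 1847) and ectoderm E12.5 minus E11.5 (4152, highest other 2166), so chance was excluded in each.

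For frontonasal minus maxillary ectoderm 10 of 100 splits gave as many as the real 1337, with a highest other of 2839, so chance was not excluded. For ectoderm E11.5 minus E10.5 there are 10 splits, too few for a share under 0.05, and 1, the real one, gave 2662, with a highest other of 42.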
